A study of Mus musculus with 12 samples.

How the data were processed

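The samples were 12 RNA-seq libraries of mouse bone marrow-derived macrophages, macrophages grown from the marrow of C57BL/6 males for 7 days in medium with 10% serum and 10 ng/mL macrophage colony stimulating factor (M-CSF). The treatment was monophosphoryl lipid A (MPLA), a lipopolysaccharide derivative of low toxicity that acts through Toll-like receptor 4. There were 3 libraries in each of 4 groups, namely untreated controls, cells after 4 h of MPLA, cells after 24 h of MPLA and cells harvested 3 d after the end of priming. Libraries were made with a stranded kit from polyadenylated RNA, per the labels' protocols. The labels do not state how long the last group was primed, when its controls were harvested or whether the 3 libraries of a group came from separate animals or cultures. The p-values therefore measure the spread between these libraries, which may be technical.

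The submitters' processing notes name bcl2fastq, TopHat2, HTSeq, edgeR, DESeq2 and DESeq without versions, and the genome build mm10. Neither the counting settings, nor the use of strand, nor the annotation release are given in the sources used here. What was used here are 3 comparison tables, 1 for each MPLA group against the same 3 controls, with 1 row per gene and no values per library. Per the file headers, the authors computed for each gene a log2 fold change, a p-value and an adjusted p-value with DESeq2, the same quantities with edgeR, an unscaled log2 ratio of the groups, and scores from baySeq, namely a likelihood of no change and its adjusted form. Each of the authors' deposited tables was normalized on its own. Differences were therefore tested only within a table, and values set side by side for different times carry no test of their difference.

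The deposited log2 values were control over MPLA, and their sign was turned here to MPLA over control. The direction was settled from the order of the groups in the comparisons and from the values, because cytokine and interferon-response genes that lipid A induces had strongly negative deposited log2 values. Those lists are for that reason not independent evidence of direction.

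Depth per library and per gene is unknown here, since the authors' deposited tables hold no counts and no mean level. Only a relative depth could be read, from the near-constant difference between the log2 fold change the authors obtained with edgeR and their unscaled log2 ratio. Because expression level was not known, folds of weakly expressed genes are less reliable than their size shows, and the log2 fold changes from the authors' DESeq2 step lie closer to 0 than the unscaled ratio for such genes. A gene without reads in 1 of the groups has an infinite unscaled ratio, and it is described below as listed at 0 in that group, with no fold.

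The tests planned before the data were examined needed counts and could not be run on these values. The planned quasi-likelihood tests, the comparisons of 24 h with 4 h and of 3 d with 24 h, the joint model of 12 libraries, the left-out libraries, the block on the replicate number and the test on other splits of the libraries were thus not run. In their place the authors' deposited p-values were used. A gene was called when the adjusted p-value from DESeq2 in the authors' deposited table was under 0.05, and an adjusted p-value given there as NA was kept as not tested. The DESeq2 columns of the authors' deposited tables were taken as the main ones, after the tables were seen, because that tool corrects for the makeup of the libraries, as the planned scaling would have done. The edgeR columns of the authors differ from them by nearly 1 constant per table and are taken here for the planned scaling by library size. Which library sizes the authors gave to edgeR is not given in the sources used here, and the edgeR columns also differ in their test, so neither part can be told from the other. Further alternatives were Benjamini-Hochberg adjustment of all deposited p-values without the NA filter, the baySeq error rate under 0.05, and calls made by all 3 methods.

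Gene lists were fixed before the data were examined, 21 lists of pathways and functions and 10 lists of cell type markers. For each list the called members were counted over all genes tested and again with Benjamini-Hochberg adjustment over the list alone. Whether a list stood apart from the other tested genes was asked with cameraPR of limma 3.58.1 in R 4.3.3 on a signed normal statistic made from the deposited p-values, with a preset correlation between genes of 0.01, over genes with an adjusted p-value. The resulting p-values were adjusted over 85 tests, those of all lists with at least 3 tested members at each time. A preset correlation of 0.05, ranks, the log2 fold changes and the authors' edgeR columns were the alternatives. A correlation estimated from the data needs values per library, so no list call was checked against an estimated correlation.

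On simulated statistics for the 17523 tested genes of the 4 h table, with 200 genes shifted by 5 standard errors, 92.5% of these genes and both shifted lists were recovered and 0 of 100 unshifted lists was called, while 7.96% of the genes called were unshifted. For the 16442 genes at 24 h the share was 93.0% with 7.92% of calls unshifted, and for the 15111 genes at 3 d it was 94.0% with 5.05%, again with both shifted lists recovered and 0 of 100 others called. The simulated statistics were drawn independently for each gene, with far fewer changed genes than the data. They therefore give no error rate for the list tests on the data.

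Overlaps of calls between tables were set beside the overlap of independent lists. Correlations and covariances between tables were set beside 100 simulations of unchanged groups against shared controls. The simulations used the standard error implied by each deposited p-value and gave the controls a share of 0.5 of the smaller variance.

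Genes are named by a rule. The rule fixed beforehand asked for a minimum level and for separation of all libraries, neither of which could be read. It was replaced after the tables were seen. The new rule asked for calls in the same direction by DESeq2 and edgeR, a call by baySeq and reads in both groups in the authors' deposited tables. Model gene symbols were left out, and the 10 largest changes each way were taken for each comparison. For each list up to 4 called members were taken per comparison, the 2 highest and the 2 lowest, and 19 genes fixed beforehand were named wherever listed. Some genes that the rule selects are not reported here. Gene positions are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, matched by gene identifier. Of the 231 named or mitochondrial genes, 27 shared at least 10% of their 50-base windows with transcripts of another gene. Their values are uncertain wherever they are named, also where no remark is made. Examples are Tfb2m (31.9%), Fpr2 (31.5%), H2-DMb2 (24.8%), Pcna (19.1%), Idi1 (17.7%) and Suclg2 (16.0%). A further check of the 231 genes found 23 with at least 10% of their exonic bases inside exons of another gene, 4 of them on the same strand, including Pfkm and Tm7sf2. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.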

Results

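RNA-seq profiles of 12 libraries of cultured mouse macrophages were compared, 3 from untreated controls and 3 each from cells exposed to MPLA for 4 h, exposed for 24 h, or harvested 3 d after the end of priming. MPLA is a lipid A derivative that signals through Toll-like receptor 4, the receptor of bacterial lipopolysaccharide. The design addresses how the transcriptome changes early and late during exposure, and what remains of the change days after it ended. All fold changes are MPLA over control and, with their adjusted p-values, come from the DESeq2 columns of the authors' deposited tables unless edgeR is named.

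The authors' deposited table for 4 h listed 21893 genes, that for 24 h 21923 and that for 3 d 23248, of which 17523, 16442 and 15111 had an adjusted p-value. Depth per library is unknown, but the constants in the authors' deposited tables implied libraries at 3 d that were 2.32 times as deep as the controls, against 0.859 times at 4 h and 0.934 times at 24 h. In the authors' deposited tables the median log2 change of all tested genes was -0.04, -0.05 and -0.02 at 4 h, 24 h and 3 d with DESeq2, and -0.97, -0.46 and -0.15 with edgeR. Directions of weakly changed genes, above all at 4 h, are therefore relative to the scaling, and both values are given where the sign of a called gene turned.

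At 4 h inflammatory cytokine and interferon-response genes were far higher than in the controls. Il6, Il12b, Nos2 and Ptgs2 were among the largest increases, and Frat2, Bmf and Cebpa among the largest decreases. Il6, which encodes the cytokine interleukin 6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), was 5978-fold higher in the authors' deposited table, with a log2 change of 12.55 and a DESeq2 adjusted p of 9.15e-248. Il12b, a subunit of interleukins 12 and 23, was higher by 12.57 on the log2 scale in the authors' deposited table. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), was higher by 12.13, and Ptgs2, the inducible cyclooxygenase, by 12.15, both in the authors' deposited table. The other largest increases in the authors' deposited table were Cxcl9 (12.11), Edn1 (12.05), Lipg (11.71), Serpina3g (11.56), Adamts4 (11.26) and Ccl22 (11.14). Serpina3g shared 15.5% of its 50-base windows with transcripts of other genes, so its value is uncertain. Among decreases, Frat2 (ENSMUSG00000047604, chromosome 19, 41845972 to 41848132) was 247-fold lower in the authors' deposited table, with a DESeq2 adjusted p of 2.988e-24. Bmf, a pro-apoptotic member of the Bcl2 family, had a log2 change of -7.44 and Cebpa, a transcription factor of myeloid differentiation, -6.73 in the authors' deposited table. Engase (-7.23), Plekhg3 (-7.13), Zfp395 (-6.93), Fam214a (-6.91), Angptl4 (-6.83), Rtn4rl1 (-6.74) and Slc26a11 (-6.60) completed the largest decreases in the authors' deposited table.

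In the authors' deposited table for 4 h, 5579 genes were higher and 5438 lower at a DESeq2 adjusted p under 0.05, and 3172 and 3243 of them changed at least 2-fold. With edgeR 1926 higher and 7863 lower genes changed at least 2-fold in the authors' deposited table. The edgeR columns of the authors' deposited table gave 2949 higher and 10965 lower, so the share of higher genes among those called was 50.6% with DESeq2 and 21.2% with edgeR. Of the 5579 genes higher with DESeq2, 2913 were also higher and 1941 were lower with edgeR in the authors' deposited table, while all 5438 lower genes were lower with both. Of the 1414 genes listed at 0 in the controls, 227 were called higher in the authors' deposited table, and 139 of the 3077 listed at 0 after MPLA were called lower.

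**Figure D1:**
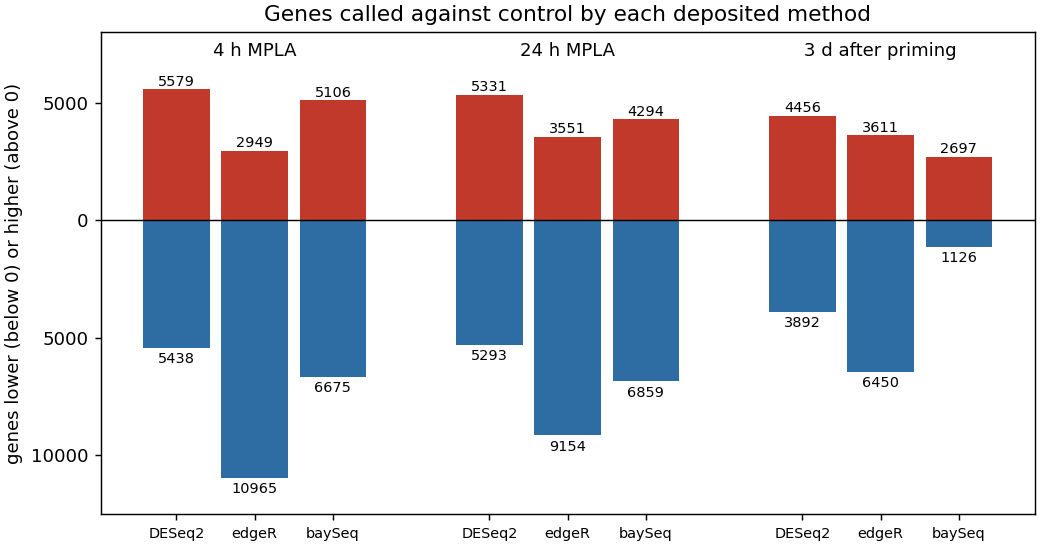
Bars show the number of genes called higher (red, above 0) or lower (blue, below 0) with MPLA than in the controls at each time, by the DESeq2, edgeR and baySeq columns of the authors' deposited tables, with adjusted p or error rate under 0.05. The direction of a baySeq call is the sign of the DESeq2 change. At 4 h DESeq2 gave 5579 higher and 5438 lower, and edgeR 2949 and 10965.

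Counts of list members are given over all genes tested, and the count adjusted over the list alone was the same unless it is given too. Of 28 inflammatory cytokines and chemokines, 26 rose at 4 h and 0 fell in the authors' deposited table (limma cameraPR, adjusted p = 8.29e-20), among them Tnf (8.19), Il1b (8.11), Il6 and Il12b. All 40 type I interferon response genes rose in the authors' deposited table (adjusted p = 3.08e-43), with a median of 6.06, Cxcl9 and the chemokine gene Cxcl10 (10.87) highest and Ifnb1, interferon beta itself, at 8.90. These lists served to settle the sign of the tables and are not independent evidence of direction. Of 26 feedback inhibitors of inflammatory signalling, 22 rose and 4 fell in the authors' deposited table (adjusted p = 9.48e-13), or 18 and 7 with edgeR, with Socs1 (8.21) and Socs3 (7.89), suppressors of cytokine signalling, highest and Inpp5d (-4.07) and Sigirr (-3.08) lowest. Il10, an anti-inflammatory cytokine, had a log2 change of 4.27 in the authors' deposited table. Of 36 Toll-like receptor and signalling genes, 29 rose and 6 fell in the authors' deposited table (adjusted p = 2.60e-13), or 24 and 12 with edgeR. Tlr3 (4.17) and Nfkb2 (4.04) were highest and Tlr13 (-2.33) and Tab1 (-1.70) lowest in the authors' deposited table. Tlr4, the receptor for MPLA, stood at -0.08 with a DESeq2 adjusted p of 0.159 and at -1.01 with edgeR in the authors' deposited table.

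Genes of host defence and antigen presentation were also read at 4 h. All 16 genes of MHC class I presentation and the immunoproteasome rose in the authors' deposited table (adjusted p = 1.10e-21), among them Nlrc5 (4.84), the transactivator of class I genes, and H2-Q7 (4.31), 26.4% of whose windows are shared with other genes. Of 14 MHC class II and costimulatory genes, 10 rose and 1 fell in the authors' deposited table (adjusted p = 0.0087), but 6 rose and 5 fell with edgeR. Cd40 (9.72) and Ciita (4.18) were highest and H2-DMb2 (-2.23) lowest in the authors' deposited table. Of 23 oxidative burst and antimicrobial genes, 16 rose and 2 fell in the authors' deposited table (17 and 2 adjusted over the list alone; cameraPR adjusted p = 1.56e-08; 13 and 6 with edgeR), with Nos2 and Iigp1 (9.11) highest and Slc11a1 (-0.38) among those that fell. Of 23 phagocytic receptors, 18 rose and 5 fell in the authors' deposited table (adjusted p = 2.96e-05), while 11 rose and 12 fell with edgeR, where the list test gave an adjusted p of 0.0521. Fpr2 (6.45), a formyl peptide receptor, was highest among those with reads in both groups, and Stab1 (-1.20) and Scarb1 (-1.01) were lowest in the authors' deposited table. Timd4, a phagocytic receptor for phosphatidylserine, was called higher in the authors' deposited table and listed at 0 in the controls. Of 16 alternative activation genes, 7 rose and 5 fell in the authors' deposited table (adjusted p = 0.971), but 5 rose and 8 fell with edgeR. The median was 0.27 with DESeq2 and -0.62 with edgeR in the authors' deposited table, and cameraPR placed the list below the other genes with both. Those with the largest changes in the authors' deposited table were Ccl17 (6.85) and Klf4 (2.67), the highest, and the scavenger receptor gene Cd163 (-4.21) and Pparg lowest. Pparg was 8.00-fold lower in the authors' deposited table. Arg1, arginase 1, stood at 0.13 with DESeq2 and -0.72 with edgeR in the authors' deposited table and passed neither test.

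Metabolic genes split at 4 h. Irg1, also called Acod1, which makes itaconate (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573), was 1088-fold higher in the authors' deposited table, with an adjusted p below the smallest number stored. Of 21 genes of itaconate, nitric oxide and amino acid metabolism, 14 rose and 3 fell in the authors' deposited table (15 and 3 adjusted over the list alone; cameraPR adjusted p = 3.49e-07; 13 and 7 with edgeR), the lowest being Slc1a5 (-0.92) and Got1 (-0.87). Of 20 glycolysis and lactate export genes, 13 rose and 4 fell with DESeq2 (adjusted p = 0.00378), but 7 rose and 12 fell with edgeR (adjusted p = 0.50), both in the authors' deposited table. Pfkfb3 (3.12), Pfkp (2.92), Hk2 (2.24) and the glucose transporter gene Slc2a1 (2.14) were higher with both, Pfkm (-2.08) and Gpi1 (-0.71) were lower with both, and Ldha turned from 0.26 to -0.67 in the authors' deposited table. Of 10 pentose phosphate genes, 2 rose and 6 fell in the authors' deposited table (adjusted p = 0.826), or 1 and 9 with edgeR, with Rpe (2.12) highest, Pgd at 0.45 with DESeq2 and -0.49 with edgeR, and Shpk (-2.13) and Prps2 (-0.90) lowest.

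For mitochondrial genes at 4 h the direction differed between the tools. Of 72 nuclear-encoded oxidative phosphorylation genes, 48 rose and 8 fell with DESeq2 (49 and 8 adjusted over the list alone; cameraPR adjusted p = 0.104), and 2 rose and 67 fell with edgeR, both in the authors' deposited table. Cycs, cytochrome c (3.56), and Cox5a (1.21) were higher with both tools and Ndufs7 (-0.55) and Ndufv3 (-0.49) lower with both in the authors' deposited table, and Cycs shared 25.9% of its windows with other genes. Of 13 mitochondrially encoded genes, 7 rose and 0 fell with DESeq2 (adjusted p = 0.546) and 0 rose and 9 fell with edgeR in the authors' deposited table, where mt-Co1 stood at 0.54 and -0.39 and mt-Nd4 at 0.48 and -0.46. Of 25 pyruvate dehydrogenase and TCA cycle genes, 14 rose and 7 fell with DESeq2 (adjusted p = 0.787) and 1 rose and 23 fell with edgeR (adjusted p = 0.0196), both in the authors' deposited table. Dld (1.18) was highest, Pdhx stood at 0.81 and -0.13, and Pcx (-0.94) and Idh3g (-0.73) were lowest in the authors' deposited table. Of 18 mitochondrial biogenesis genes, 8 rose and 5 fell in the authors' deposited table (9 and 6 adjusted over the list alone; cameraPR adjusted p = 0.787), while 2 rose and 14 fell with edgeR. Ppargc1b (3.66), a coactivator of mitochondrial genes, and Gabpb1 (1.74) were highest and Peo1 (-2.32) and Top1mt (-1.01) lowest in the authors' deposited table, and Tfam turned from 0.52 to -0.41 with edgeR. Ppargc1a was listed at 0 after 4 h and 24 h of MPLA in the authors' deposited tables, was not called by DESeq2 and was called lower by edgeR.

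Of 27 mTOR pathway genes, 10 rose and 15 fell at 4 h in the authors' deposited table (adjusted p = 0.489), while 4 rose and 22 fell with edgeR (adjusted p = 0.00974). Rictor (2.62) was among the highest, the mTORC1 inhibitors Sesn1 (-4.90) and Ddit4 (-4.33) were lowest, and Mtor turned from 0.78 to -0.16 with edgeR in the authors' deposited table. Of 20 HIF-1 and hypoxia targets, 8 rose and 12 fell in the authors' deposited table (adjusted p = 0.787), with P4ha1 (2.79) higher, Adm called higher but listed at 0 in the controls, Ankrd37 (-2.83) and Vegfa (-2.44) lowest, and Hif1a at 1.76. The HIF-1 list had a median of -0.30 in the authors' deposited table, while cameraPR placed it above the other genes. Of 17 fatty acid oxidation genes, 3 rose and 11 fell in the authors' deposited table (adjusted p = 0.105), while 0 rose and 17 fell with edgeR (adjusted p = 3.33e-04). Echs1 (-1.56) and Acadm (-1.30) were lowest, and Acadl turned from 0.76 to -0.18 and Etfa from 0.61 to -0.33 with edgeR in the authors' deposited table. Of 23 cholesterol genes, 13 rose and 7 fell in the authors' deposited table (adjusted p = 0.00949), while 9 rose and 11 fell with edgeR (adjusted p = 0.235). Dhcr7 (-2.42) and Mvk (-1.01) were lowest in the authors' deposited table. Of 32 cell cycle genes, 6 rose and 26 fell in the authors' deposited table (adjusted p = 1.50e-05; 2 and 29 with edgeR), with the mitotic genes Bub1b (-3.72) and Cdc20 (-3.55) lowest, Ccne1 (1.45) and Pcna (1.17) highest, and Mki67 at -0.35.

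**Figure D2:**
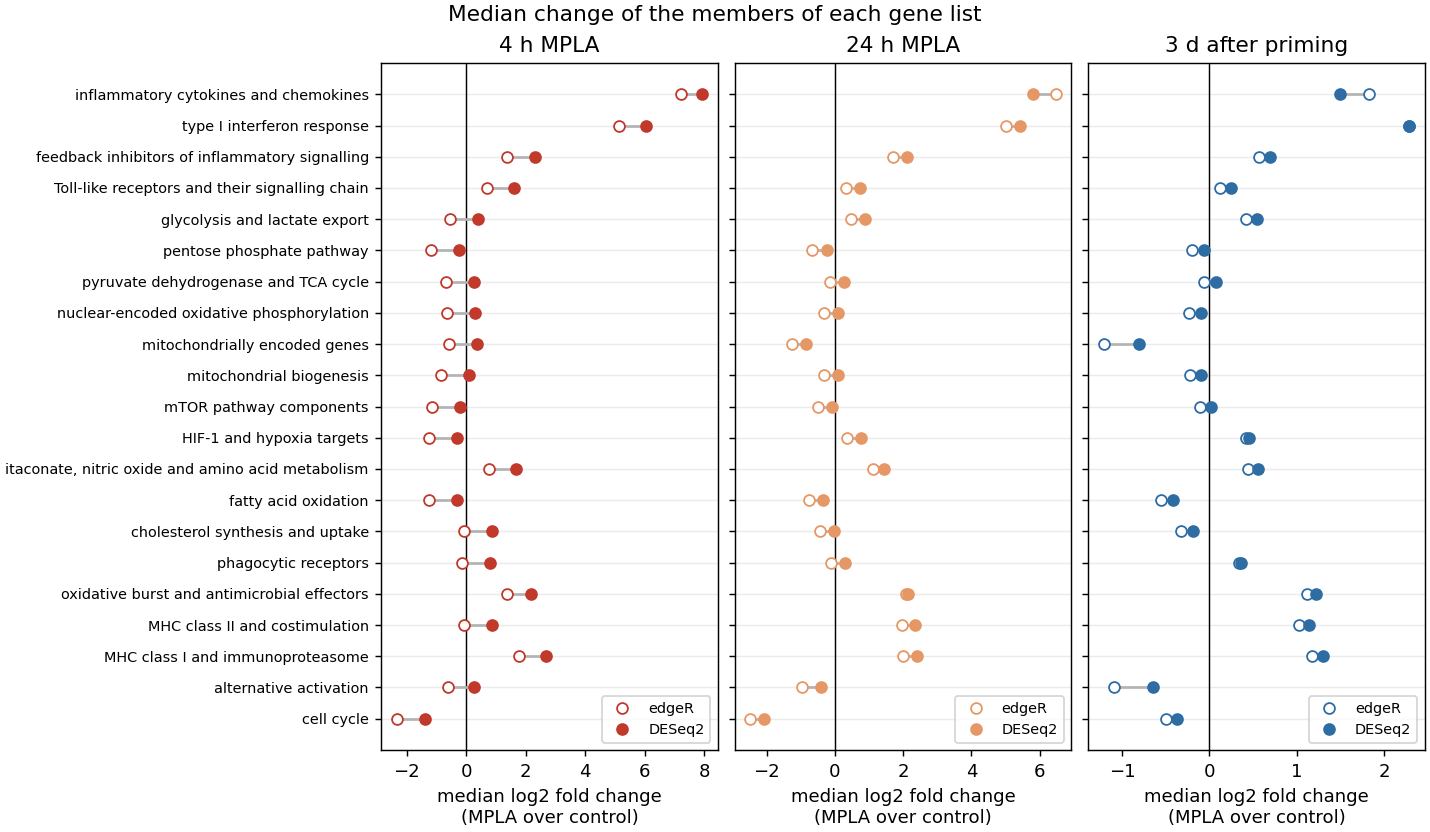
Each point is the median log2 fold change (MPLA over control) of the listed members of a gene list in the authors' deposited tables, filled for DESeq2 and open for edgeR, with 1 panel per time and a separate scale on each x axis. The interferon response list had DESeq2 medians of 6.06, 5.43 and 2.29 at 4 h, 24 h and 3 d, while the mitochondrially encoded genes had -0.85 at 24 h and -0.81 at 3 d.

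After 24 h of MPLA inflammatory, interferon-response and antigen presentation genes were higher than in the controls, and cell cycle genes were lower. Saa3 and Lcn2 stood beside Cxcl11 and Nos2 among the largest increases, and Ighm, Hpgd and Ccnb2 were among the largest decreases. Cxcl11 (10.88), Slfn4 (10.73), Nos2 (10.39), Slfn1 (10.35), the chemokine gene Ccl5 (9.85), Saa3 (9.78), Adora2a (9.75), Il12b (9.72), Il1a (9.65) and Lcn2 (9.63) were the largest increases in the authors' deposited table. Saa3, which encodes an acute-phase serum amyloid A (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), was 881-fold higher in the authors' deposited table, and Lcn2, which encodes a protein that binds bacterial siderophores (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), was 794-fold higher with a DESeq2 adjusted p of 4.929e-209. Slfn4 shared 10.8% of its windows with other genes, and 41.7% of the exonic bases of Cxcl11 lie within exons of a gene on the opposite strand, so both values are uncertain. The largest decreases in the authors' deposited table were Ighm (-8.98), Gprc5c (-8.60), Hpgd (-8.17), Ccnb2 (-7.76), Samd4 (-7.74), Aspm (-7.67), Gpr34 (-7.57), Pif1 (-7.42), Frat2 (-7.28) and Ankle1 (-6.98). Hpgd, which degrades prostaglandins (ENSMUSG00000031613, chromosome 8, 56294585 to 56321043), was 289-fold lower in the authors' deposited table with a DESeq2 adjusted p of 5.267e-40. Ccnb2 encodes a mitotic cyclin and was 217-fold lower in the authors' deposited table.

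The authors' deposited table for 24 h held 5331 higher and 5293 lower genes by DESeq2, of which 2106 and 2699 changed at least 2-fold, against 1660 and 4868 with edgeR. With edgeR the authors' deposited table gave 3551 higher and 9154 lower, a share of higher genes of 27.9% against 50.2% with DESeq2. Of the genes higher with DESeq2, 3425 were higher and 800 lower with edgeR in the authors' deposited table.

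The inflammatory and interferon lists remained raised at 24 h. Of 28 cytokines and chemokines 25 rose and 0 fell in the authors' deposited table (adjusted p = 8.29e-20), with Tnf at 5.36, Il1b at 7.07 and Il6 at 8.95. All 40 interferon response genes rose (adjusted p = 1.19e-51), including Oasl1 (9.29), Cxcl10 (8.36) and Ifnb1 (5.65) in the authors' deposited table. Of the feedback inhibitors 22 of 26 rose and 4 fell in the authors' deposited table (adjusted p = 1.76e-14), with Il1rn (6.75), the interleukin 1 receptor antagonist, and Socs1 (6.20) highest and Sigirr (-2.60) and Sh2b3 (-0.44) lowest, while Il10 stood at 2.62. Of the Toll-like receptor and signalling genes 28 of 36 rose and 7 fell in the authors' deposited table (28 and 8 adjusted over the list alone; cameraPR adjusted p = 2.54e-07; 21 and 11 with edgeR), with Tlr1 (3.34) and Tlr3 (2.86) highest, Tlr8 (-0.61) and Irak4 (-0.58) lowest and Tlr4 at -0.38. Tlr1 shared 15.4% of its windows with other genes.

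All 16 MHC class I and immunoproteasome genes rose at 24 h in the authors' deposited table (adjusted p = 2.12e-29), with H2-Q7 at 8.10 and H2-Q4 at 4.18, both of which share sequence with related class I genes. Of 14 MHC class II and costimulatory genes 12 rose and 1 fell in the authors' deposited table (adjusted p = 3.11e-07; 9 and 2 with edgeR), with Cd40 (6.59) and H2-Ab1 (3.73) highest and H2-DMb2 (-0.84) lowest. Of 22 antimicrobial genes listed, 18 rose and 2 fell in the authors' deposited table (adjusted p = 4.06e-15), and the 2 that fell were the lysozyme genes Lyz2 (-1.50) and Lyz1 (-1.19), which share sequence with each other. Of 23 phagocytic receptors 13 rose and 9 fell in the authors' deposited table (14 and 9 adjusted over the list alone; cameraPR adjusted p = 0.153), but 11 rose and 12 fell with edgeR. The extremes in the authors' deposited table were Fpr1 (7.67) and Fpr2 (6.98), the highest, and Mrc1 (-5.67), the mannose receptor (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), and Clec7a (-3.19), the beta-glucan receptor dectin, the lowest. Of 16 alternative activation genes 5 rose and 6 fell in the authors' deposited table (adjusted p = 0.0726; 4 and 8 with edgeR), among them Ccl17 (4.73), Arg1 (2.14), Mrc1 and Cd163 (-5.24).

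Glycolysis genes were higher with both tools at 24 h. Of 20 genes 16 rose and 4 fell in the authors' deposited table (adjusted p = 1.23e-07), and 15 rose and 4 fell with edgeR. On log2 fold changes the call was lost (cameraPR adjusted p = 0.112). Pfkfb3 (2.96), Hk3 (2.25), Slc2a1 (2.21), Hk2 (1.12) and Ldha (1.05) were higher, and Aldoc (-2.95) and Pfkm (-1.05) lower in the authors' deposited table. Irg1 stood at 9.39 and Nos2 at 10.39, and 14 of the 21 itaconate, nitric oxide and amino acid genes rose while 5 fell in the authors' deposited table (adjusted p = 1.80e-05), with Sat1 (-1.70) and Slc1a5 (-1.25) lowest. In the pentose phosphate list 4 of 10 rose and 5 fell in the authors' deposited table (4 and 6 adjusted over the list alone; cameraPR adjusted p = 0.787; 2 and 6 with edgeR). Rpe (1.38) and G6pdx (0.70) were highest and Prps2 (-1.58) and Shpk (-1.09) lowest in the authors' deposited table. Of 20 HIF-1 targets 11 rose and 6 fell in the authors' deposited table (adjusted p = 0.308), with Slc2a1 highest among those with reads in both groups, Ndrg1 (-3.97) and Mxi1 (-2.79) lowest, and Hif1a at 1.04.

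Mitochondrially encoded genes fell at 24 h with both tools, and nuclear genes of the same complexes went both ways, with a balance that turned between the tools. Of 13 mitochondrially encoded genes 0 rose and 9 fell with DESeq2 (0 and 10 adjusted over the list alone; cameraPR adjusted p = 0.00189), and 0 rose and 12 fell with edgeR, both in the authors' deposited table. The list did not pass on log2 fold changes, where the cameraPR adjusted p was 0.0890. The lowest called were mt-Atp6 (-1.43) and mt-Co3 (-1.41) in the authors' deposited table, both of which share over 99% of their windows with nuclear copies. Over the 6 mitochondrial genes that share under 10%, the median was -0.84 and 5 were called lower in the authors' deposited table, with mt-Cytb at -1.12 (chromosome M, 14145 to 15288). Of 72 nuclear-encoded oxidative phosphorylation genes 34 rose and 18 fell with DESeq2 (35 and 18 adjusted over the list alone; cameraPR adjusted p = 0.598), and 8 rose and 49 fell with edgeR, both in the authors' deposited table. Cycs (3.15) and Cox5a (1.44) were highest and Uqcr11 (-0.97) and Ndufb11 (-0.92) lowest in the authors' deposited table. Of 25 TCA cycle genes 13 rose and 8 fell in the authors' deposited table (adjusted p = 0.787), against 7 and 13 with edgeR, with Mdh2 (1.07) and Pdhx (0.81) highest and Idh2 (-1.68) and Suclg2 (-1.47) lowest. Of 18 biogenesis genes 7 rose and 5 fell in the authors' deposited table (adjusted p = 0.798), against 4 and 11 with edgeR, with Pprc1 (1.44) and Ppargc1b (1.27) highest, Tfb2m (-0.93) and Peo1 (-0.57) lowest, and Tfam at 0.36 with DESeq2 and -0.06 with edgeR. Tfb2m shared 31.9% and Suclg2 16.0% of their windows with other genes.

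Of 17 fatty acid oxidation genes 2 rose and 12 fell at 24 h in the authors' deposited table (adjusted p = 0.0195), and 0 rose and 17 fell with edgeR. The call was lost with a preset correlation of 0.05 (cameraPR adjusted p = 0.0768) and on log2 fold changes (0.506). Hadh (-1.39) and Acaa2 (-1.33) were lowest, and the 2 called higher with DESeq2, Acadl (0.29) and Slc25a20 (0.19), turned to -0.12 and -0.23 with edgeR in the authors' deposited table. Of 27 mTOR pathway genes 12 rose and 13 fell in the authors' deposited table (adjusted p = 0.504), against 6 and 17 with edgeR, with Rictor (1.38) and Pik3cb (1.20) highest, Sesn1 (-4.21) and Deptor (-3.77) lowest, and Mtor at 0.37 with DESeq2 and -0.04 with edgeR. Of 23 cholesterol genes 10 rose and 8 fell in the authors' deposited table (adjusted p = 0.758), against 4 and 14 with edgeR, with Hsd17b7 (1.39) among the highest and Tm7sf2 (-1.37) and Dhcr7 (-0.84) lowest. The cholesterol list had a median of -0.02 in the authors' deposited table, while cameraPR placed it above the other genes. Of 32 cell cycle genes 5 rose and 27 fell in the authors' deposited table (adjusted p = 8.37e-11), with Ccnb2 (-7.76) and Cdc20 (-6.49) lowest, Ccne1 (1.65) and Cdt1 (0.80) highest and Mki67 at -2.21.

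At 3 d after priming ended, antimicrobial, interferon-response and antigen presentation genes were still higher, while DESeq2 called neither Il12b nor Cxcl9. The largest increases in the authors' deposited table were Saa3 (8.22), Lcn2 (7.27), Lox (7.22), Ccl5 (6.91), H2-Q6 (6.67), H2-Q7 (6.59), Fpr1 (6.17), Ly75 (6.05), Cd38 (6.03) and Slfn1 (5.99). Saa3 was 298-fold, Lcn2 154-fold and Ccl5 120-fold higher in the authors' deposited table. Lox encodes lysyl oxidase, a crosslinker of collagen (ENSMUSG00000024529, chromosome 18, 52516067 to 52529867). H2-Q6 and H2-Q7 share 32.0% and 26.4% of their windows with other genes and cannot be taken as independent values. The largest decreases in the authors' deposited table were Ighm (-6.42), Hpgd (-6.22), Slco2b1 (-5.52), Gprc5c (-4.90), Gpr34 (-4.69), Plxdc2 (-4.57), Baiap2l2 (-4.37), Myh15 (-4.05), Atp6v0d2 (-3.97) and Asb10 (-3.65). Ighm, the constant region of the immunoglobulin heavy chain mu (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), was 85.6-fold lower in the authors' deposited table, with an adjusted p below the smallest number stored.

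The authors' deposited table for 3 d held 4456 higher and 3892 lower genes by DESeq2, of which 964 and 786 changed at least 2-fold, against 1044 and 1598 with edgeR. With edgeR the authors' deposited table gave 3611 and 6450, and with baySeq 2697 and 1126, so the share of higher genes was 53.4%, 35.9% and 70.5% in turn. The baySeq directions are the signs of the DESeq2 changes and are not separate evidence of direction. The deeper libraries of this group were compared with the same controls, and the labels do not give the age in culture of the controls.

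Of 27 cytokines and chemokines listed, 20 rose and 1 fell at 3 d in the authors' deposited table (adjusted p = 3.59e-15), led by Ccl5 and Tnfsf15 (4.06), with Il18 (-0.24) the 1 that fell. Il1b was 2.82-fold higher in the authors' deposited table. Tnf stood at 2.07 and Il6 at 1.32 in the authors' deposited table, while Il10 (0.43) was not called and Il12b (0.13) had no adjusted p. Of 40 interferon response genes 39 rose in the authors' deposited table (adjusted p = 2.49e-61), with Oasl1 (5.48) and Ifi44 (5.19) highest, Cxcl10 at 2.44 and Ifnb1 at 1.61. The other was Cxcl9, at -0.63 with a DESeq2 adjusted p of 0.221 in the authors' deposited table. Of 26 feedback inhibitors 18 rose and 2 fell in the authors' deposited table (adjusted p = 7.99e-15), or 16 and 7 with edgeR, with Cd274 (2.98), which encodes PD-L1, and Il1rn (2.57) highest and Sh2b3 (-0.47) and Zfp36 (-0.12) lowest. Of 36 Toll-like receptor and signalling genes 19 rose and 8 fell in the authors' deposited table (19 and 9 adjusted over the list alone; cameraPR adjusted p = 1.97e-05, and 0.0890 on log2 fold changes; 18 and 12 with edgeR), with Tlr2 (1.43) and Ikbke (1.31) highest, Irak4 (-0.35) and Tab1 (-0.34) lowest and Tlr4 at -0.16.

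All 16 MHC class I and immunoproteasome genes were higher at 3 d in the authors' deposited table (adjusted p = 3.32e-39), as were 12 of 14 MHC class II and costimulatory genes with 0 lower (adjusted p = 4.06e-09), led by H2-Aa (2.62) and H2-Ab1 (2.54). Of 23 antimicrobial genes 18 rose and 3 fell in the authors' deposited table (adjusted p = 2.41e-22), again with Lyz2 (-1.43) and Lyz1 (-0.71) lowest. Of 23 phagocytic receptors 13 rose and 9 fell in the authors' deposited table (adjusted p = 0.0461, and 0.0984 with edgeR), with Fpr1 and Fpr2 (4.53) highest and Clec7a (-1.53) and Mrc1 (-1.31) lowest. Fpr2 shared 31.5% of its windows with other genes. Of 16 alternative activation genes 3 rose and 8 fell in the authors' deposited table (4 and 8 adjusted over the list alone; cameraPR adjusted p = 2.26e-05, and 0.0582 on ranks), with Cd163 (-3.45) and Ccl24 (-3.17) lowest and Tgm2 (0.86) and Klf4 (0.45) highest.

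Glycolysis genes were also higher at 3 d, 15 of 20 rising and 3 falling in the authors' deposited table (adjusted p = 1.56e-07), with Pfkfb3 (2.18) and Slc16a3 (1.13), a lactate exporter, highest and Slc16a1 (-0.45) and Pfkm (-0.44) lowest. Slc2a1 (0.81), Hif1a (0.71) and Ldha (0.59) were higher, while Hk2 stood at 0.04 and was not called in the authors' deposited table. Irg1 (4.80) and Nos2 (5.72) remained the highest of the itaconate, nitric oxide and amino acid genes, of which 10 rose and 6 fell in the authors' deposited table (adjusted p = 3.73e-05), with Il4i1 (-1.26) and Sat1 (-0.81) lowest. The call of that list was lost on ranks, where the adjusted p was 0.147. Of 10 pentose phosphate genes 1 rose, Rpe (0.68), and 4 fell in the authors' deposited table (adjusted p = 0.376), Taldo1 (-0.50) and Prps2 (-0.36) being lowest. Of 20 HIF-1 targets 12 rose and 6 fell in the authors' deposited table (adjusted p = 0.174). In the authors' deposited table P4ha1 (1.15) and P4ha2 (1.02) were highest and Ankrd37 (-1.25) and Ndrg1 (-1.15) lowest.

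Of 13 mitochondrially encoded genes 0 rose and 9 fell at 3 d with either tool in the authors' deposited table (adjusted p = 2.29e-04), with mt-Co3 (-1.88) and mt-Cytb (-1.28) lowest. Over the 6 that share under 10% of their windows with other genes the median was -0.79 and 5 were called lower in the authors' deposited table. Of 72 nuclear-encoded oxidative phosphorylation genes 13 rose and 34 fell with DESeq2 (14 and 34 adjusted over the list alone; cameraPR adjusted p = 0.12) and 4 rose and 48 fell with edgeR (adjusted p = 0.0201), both in the authors' deposited table, with Cycs (1.38) and Cox5a (0.57) highest and Ndufa4 (-1.01) and Uqcr11 (-0.69) lowest. Of 25 TCA cycle genes 10 rose and 7 fell in the authors' deposited table (adjusted p = 0.787), against 7 and 10 with edgeR. Its extremes in the authors' deposited table were Mdh2 (0.56) and Ogdh (0.44), the highest, and Mpc1 (-0.89) and Idh2 (-0.76), the lowest. The TCA cycle median was 0.07 with DESeq2 and -0.06 with edgeR in the authors' deposited table, and cameraPR placed the list below the other genes with both. Of 18 biogenesis genes 4 rose and 7 fell in the authors' deposited table (adjusted p = 0.787), with Ppargc1b (1.06) and Pprc1 (1.04) highest, Polg2 (-0.55) and Tfb1m (-0.49) lowest and Tfam at -0.07. Of 17 fatty acid oxidation genes 0 rose and 13 fell in the authors' deposited table (adjusted p = 1.99e-04, and 0.10 on log2 fold changes), with Acadm (-0.75) and Acaa2 (-0.75) lowest.

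Of 27 mTOR pathway genes 7 rose and 10 fell at 3 d in the authors' deposited table (adjusted p = 0.181), with Pik3cb (0.86) and Rictor (0.68) highest, Deptor (-1.42) and Sesn1 (-1.41) lowest, and Mtor at 0.09 and not called. The mTOR list had a median of 0.02 with DESeq2 and -0.11 with edgeR in the authors' deposited table, and cameraPR placed it below the other genes. Of 23 cholesterol genes 5 rose and 12 fell in the authors' deposited table (adjusted p = 0.184; 4 and 17 with edgeR). Hsd17b7 (0.39) was highest and Idi1 (-0.73) among the lowest in the authors' deposited table. Of 32 cell cycle genes 12 rose and 18 fell in the authors' deposited table (adjusted p = 0.00384, and 0.0539 with a preset correlation of 0.05; 8 and 19 with edgeR), with Ccnb2 (-1.55) and Cdc20 (-1.49) lowest, Ccnd1 (1.02) and Ccne1 (0.88) highest, and Mki67 at -0.79.

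**Figure D3:**
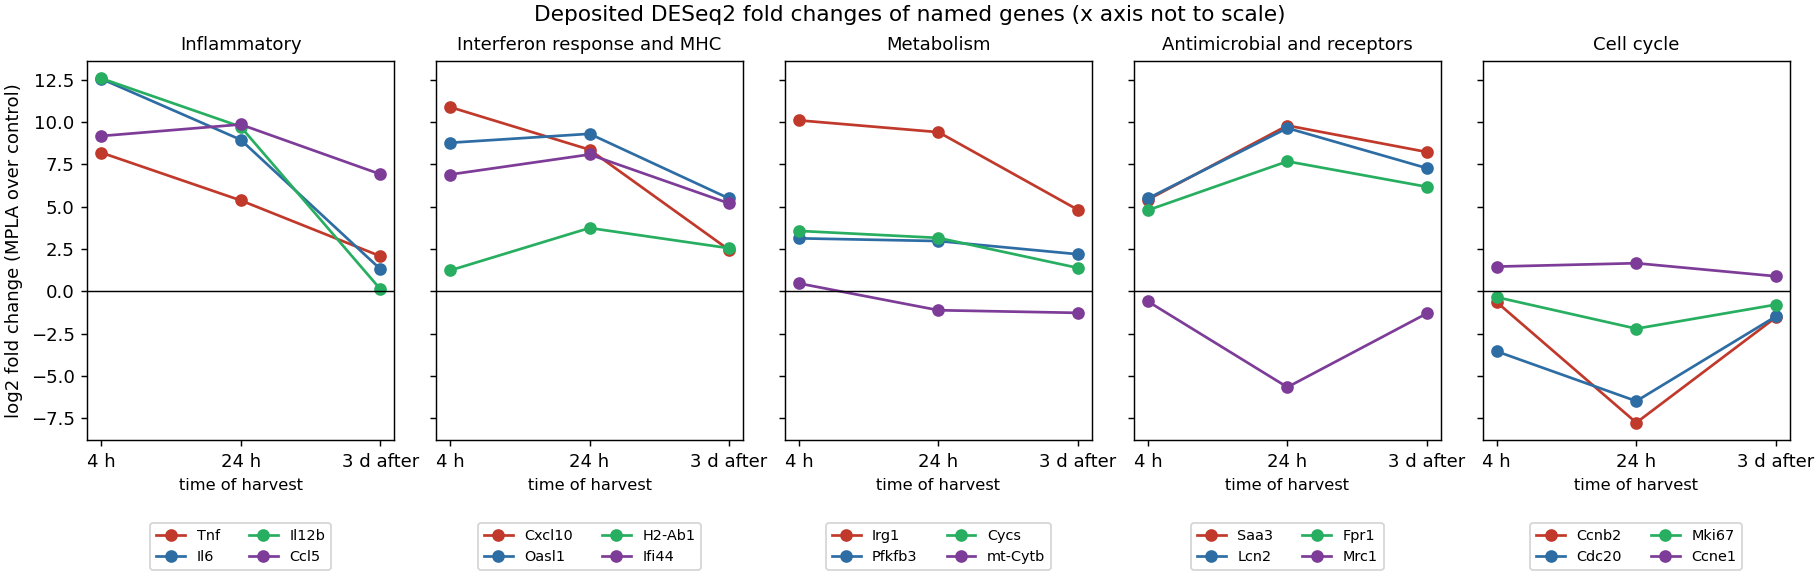
Lines join the DESeq2 log2 fold changes (MPLA over control, y axis) of 20 named genes in the authors' deposited tables at 4 h, 24 h and 3 d after priming (x axis, not to scale), with 1 panel per group of genes and no error bars since the tables give none. Saa3 and Lcn2 stood at 8.22 and 7.27 at 3 d, whereas Il6 stood at 1.32, and differences between times were not tested.

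Which of the changes at 24 h were still present 3 d after priming was asked next. Of 2106 genes at least 2-fold higher at 24 h, 1514 (71.9%) were called higher and 750 (35.6%) at least 2-fold higher at 3 d in the authors' deposited tables. Of 2699 genes at least 2-fold lower at 24 h, 1699 (62.9%) were called lower and 636 (23.6%) at least 2-fold lower at 3 d in the authors' deposited tables. The median log2 change of the first set went with 2.05 at 24 h and 0.72 at 3 d, and that of the second with -1.96 and -0.58, in the authors' deposited tables. Seen from 3 d, 799 of the 964 genes at least 2-fold higher were called higher at 24 h and 670 at 4 h, and 140 at neither time, in the authors' deposited tables. Of the 786 at least 2-fold lower at 3 d, 670 were called lower at 24 h and 494 at 4 h, and 101 at neither time, in the authors' deposited tables. The age in culture of the controls is not given, so time in culture cannot be told apart from priming in the calls at 3 d.

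Over 15068 genes tested at both times, 3317 were called higher at 24 h and at 3 d and 2974 lower at both in the authors' deposited tables, where independent lists would share 1509 and 1361. Over 21317 genes listed at both times the authors' deposited tables gave 2230 higher and 5521 lower at both with edgeR, and 2002 and 1051 with baySeq, so the balance depends on the tool. Called in opposite directions by DESeq2 were 333 genes higher and then lower and 501 lower and then higher in the authors' deposited tables. With DESeq2 and edgeR both calling the turn, these were 104 and 311 of the 21317 genes listed at both times. Across genes, which are not independent replicates, the log2 changes at 24 h and 3 d in the authors' deposited tables had a Pearson r of 0.763, a Spearman rho of 0.688 and a covariance of 0.964. Simulated unchanged groups against shared controls gave a mean r of 0.274 and a covariance of 0.026 in 100 draws. The draws gave at most 0 shared calls, which follows from simulating no change in any gene. That count therefore does not bear on how shared controls affect the overlap of called genes. The covariance beyond the simulated one was 0.939. For 4 h and 24 h r was 0.731 and the covariance 2.32, against a simulated 0.390 and 0.113, and for 4 h and 3 d r was 0.537 and the covariance 0.781, against 0.229 and 0.026, from the authors' deposited tables. All comparisons share the 3 control libraries, which were too few to split, so part of the excess over independent lists may come from them.

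Markers of macrophages and of other cells were read in the same tables. Some markers of other cells are also expressed by macrophages, among them Csf3r, Itgax, Ccr7, Kmo, Mmp9 and Acp5. A change in these need not come from other cells. Of 11 macrophage markers, 8 rose and 2 fell at 4 h, 4 rose and 7 fell at 24 h and 7 rose and 3 fell at 3 d in the authors' deposited tables, with 2 rising and 9 falling at 4 h under edgeR. The cameraPR adjusted p of this list was 0.338, 0.00325 and 0.340 in turn, the second with a lower direction. That call at 24 h was lost on ranks (adjusted p = 0.128) and on log2 fold changes (0.92). Adgre1, which encodes F4/80, stood at 1.22, 2.15 and 1.17 at the 3 times, Fcgr1 at 3.07, 3.70 and 0.98, and Csf1r, the M-CSF receptor gene, at -1.01, -1.52 and -0.54 in the authors' deposited tables. Of the neutrophil markers 1 rose and 0 fell among 11 listed at 4 h, 2 rose and 2 fell among 10 at 24 h (2 and 1 adjusted over the list alone), and 3 rose and 0 fell among 10 at 3 d in the authors' deposited tables. With edgeR 0 rose and 3 fell at 4 h, where Csf3r stood at 0.45 with DESeq2 and -0.49 with edgeR in the authors' deposited table. Of 10 dendritic cell markers 6 rose and 0 fell at 4 h, 2 rose and 3 fell at 24 h and 0 rose and 3 fell at 3 d in the authors' deposited tables, while 2 rose and 2 fell at 4 h with edgeR. Xcr1 stood at 3.93, 3.08 and 0.18 in the authors' deposited tables, and Itgax and Kmo at -2.32 and -3.30 at 3 d. Itgax turned from 0.57 to -0.37 with edgeR at 4 h in the authors' deposited table. Ccr7 was listed at 0 in the controls and called higher at 4 h and 24 h in the authors' deposited tables.

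Of the B cell markers 4, 3 and 6 were listed at 4 h, 24 h and 3 d in the authors' deposited tables, and DESeq2 called Cd79b alone, at -1.54 at 24 h and 0.47 at 3 d. At 4 h edgeR called Cd79b lower, at -1.52, and baySeq called 2 of these markers in the authors' deposited table. Of T and NK cell markers DESeq2 called 0 at 4 h and 3 d and 2 of 3 lower at 24 h, Klrb1c and Cd2, both listed at 0 after 24 h of MPLA in the authors' deposited tables. With edgeR 2 were called lower at each time in the authors' deposited tables, and 0 of 4 had a DESeq2 adjusted p at 3 d. Of 2 erythroid markers 0 was called at any time by DESeq2 or edgeR in the authors' deposited tables, Alas2 standing at 0.98 and Klf1 at -0.84 at 4 h. Of 3 mast cell and basophil markers 1 fell at 4 h, 2 at 24 h and 1 at 3 d in the authors' deposited tables, or 2, 2 and 1 with edgeR, with Kit at -1.42, -4.30 and -0.77 and Cpa3 listed at 0 at 24 h of MPLA. Of the stromal markers 3 of 8 rose at 4 h (1 adjusted over the list alone), 2 of 8 at 24 h and 1 of 7 at 3 d in the authors' deposited tables, while edgeR called 2 higher and 3 lower at 24 h. Dcn was called higher at all 3 times in the authors' deposited tables, with the controls listed at 0. Of 5 endothelial markers 2 rose and 0 fell at 4 h, 2 rose and 1 fell at 24 h and 1 rose and 1 fell at 3 d (1 and 0 adjusted over the list alone) in the authors' deposited tables, and with edgeR 2 rose and 3 fell at 4 h. Kdr stood at 4.50, 3.87 and 1.49 in the authors' deposited tables. Of 8 osteoclast markers 3 rose and 1 fell at 4 h, 1 rose and 2 fell at 24 h and 2 rose and 2 fell at 3 d in the authors' deposited tables, and 2 rose and 3 fell at 4 h with edgeR. Acp5 stood at 3.91, 3.77 and 2.88 and Atp6v0d2 at -1.23, -4.42 and -3.97 in the authors' deposited tables. Among the marker lists of other cells with at least 3 tested members, only the dendritic cell list at 3 d passed the cameraPR test, lower with an adjusted p of 0.0231, and this call was lost on ranks (adjusted p = 0.0793). Its members Itgax and Kmo are also expressed by macrophages, so the call does not by itself show a loss of dendritic cells. On log2 fold changes the mast cell and basophil list at 24 h (cameraPR adjusted p = 0.0202) and the stromal list at 3 d (3.90e-04) passed as well. The median and the direction from cameraPR differed in sign for the neutrophil and the stromal list at 4 h and for the neutrophil and the endothelial list at 24 h, and the endothelial list differed likewise at 4 h and 3 d. None of these tests passed.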

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

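The results here were picked by a rule chosen after the data were seen. It asked for calls in opposite directions at 2 times with both DESeq2 and edgeR, each at least 2-fold with DESeq2. The cases given by name were sought only among the genes named by rule and the members of the gene and marker lists. These results rest on separate tests in tables that share the controls, and the difference between the times itself was not tested. Bhlhe40, a transcription repressor gene in the hypoxia list, was called because it had a log2 change of -1.77 at 4 h and 1.08 at 24 h in the authors' deposited tables, with edgeR values of -2.73 and 0.67. Ccl24, a chemokine gene in the alternative activation list, had 2.58 at 4 h and -3.17 at 3 d in the authors' deposited tables, with edgeR values of 1.66 and -4.75. Il4i1, an amino acid oxidase gene, had 4.99 at 4 h, 1.96 at 24 h and -1.26 at 3 d in the authors' deposited tables, and so differed in direction between 3 d and each earlier time. The exons of Il4i1 lie for 83.9% of their bases within exons of Tbc1d17 on the opposite strand, which stood at -1.98, -1.06 and -0.19 in the authors' deposited tables, and the use of strand in counting is not given in the sources used here. Among all genes, 104 changed in opposite directions in this way between 4 h and 24 h, 27 between 24 h and 3 d and 104 between 4 h and 3 d, from the authors' deposited tables.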

How the results depend on the processing

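The baySeq columns, the calls by all 3 methods, and the list tests on ranks, on log2 fold changes and with a larger preset correlation were chosen after the data were seen, as was the use of the DESeq2 columns as the main ones. No paired analysis was possible because the deposited tables hold comparisons of groups and no values per library. For the same reason the planned quasi-likelihood tests, other size factors, left-out libraries, the fit of all 12 libraries, the direct comparisons of 24 h with 4 h and of 3 d with 24 h, the other splits of the libraries, the estimated correlation, fry and other pseudocounts were not run, so how many calls other splits would give is not known. The self-test used statistics and not counts, so it does not bear on the authors' models. Folds of weakly expressed genes cannot be weighed by depth here.

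Under edgeR, taken to stand for scaling by library size, the authors' deposited tables gave 2949 genes higher and 10965 lower at 4 h, 3551 and 9154 at 24 h, 6450 lower at 3 d and 5521 lower at both 24 h and 3 d. The edgeR columns change the test as well as the scaling, and the 2 parts were not separated for these counts. Only the log2 values at 4 h were compared between the tools, as given in the last section. With baySeq, and direction by the DESeq2 sign, the authors' deposited tables gave 2697 higher and 1126 lower at 3 d, and 2002 higher and 1051 lower at both 24 h and 3 d. Calls by all 3 methods in the authors' deposited tables numbered 2909 higher at 4 h, 3418 higher at 24 h, 2635 higher and 1086 lower at 3 d, and 1823 higher and 999 lower at both 24 h and 3 d. Asking for at least 2-fold at both times left 750 higher and 636 lower in the authors' deposited tables, as a stricter threshold must. Adjusting all deposited p-values without the NA filter kept each count within 1.5 times.

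Of 375 values of 223 genes selected by the naming rules, 349 kept direction and call under edgeR in the authors' deposited tables, 9 became called and 17 turned. Those that turned at 4 h in the authors' deposited table were Pgd (-0.49), Pdhx (-0.13), mt-Nd4 (-0.46), mt-Co1 (-0.39), Etfa (-0.33), Acadl (-0.18), Ldha (-0.67), Mtor (-0.16), Tfam (-0.41), Csf3r (-0.49) and Arg1 (-0.72), the last called by neither, and also Itgax (-0.37), which these rules do not select at 4 h. At 24 h they were Slc25a20 (-0.23), Acadl (-0.12), Mtor (-0.042) and Tfam (-0.059) in the authors' deposited table. At 3 d Hk2 (-0.092) and Mtor (-0.039), called by neither, turned in the authors' deposited table.

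Of 63 tests of the fixed lists other than markers, 38 passed, and 48 kept direction and side of the threshold under edgeR, 52 on ranks, 59 with the larger correlation and 52 on log2 fold changes. With edgeR the TCA cycle list turned to a lower direction at 4 h (cameraPR adjusted p = 0.0196). At 4 h edgeR also ended the calls of glycolysis (0.50), cholesterol (0.235) and phagocytic receptors (0.0521), and at 3 d that of phagocytic receptors (0.0984). It added calls, all lower, for mTOR (0.00974) and fatty acid oxidation (3.33e-04) at 4 h and nuclear oxidative phosphorylation at 3 d (0.0201). Ranks ended the calls of cholesterol at 4 h (0.0793) and, at 3 d, of itaconate and nitric oxide (0.147), phagocytic receptors (0.337), alternative activation (0.0582) and cell cycle (0.0508). They added nuclear oxidative phosphorylation, higher at 4 h (7.24e-05) and lower at 3 d (0.0362), and fatty acid oxidation, lower at 4 h (0.0297). The larger correlation ended the calls of cholesterol at 4 h (0.0644), fatty acid oxidation at 24 h (0.0768), phagocytic receptors at 3 d (0.165) and cell cycle at 3 d (0.0539). Log2 fold changes ended those of glycolysis at 4 h (0.271) and 24 h (0.112), cholesterol at 4 h (0.340), mitochondrially encoded genes at 24 h (0.0890), fatty acid oxidation at 24 h (0.506) and 3 d (0.10), Toll-like receptor signalling at 3 d (0.0890) and cell cycle at 3 d (0.119). They added phagocytic receptors at 24 h, higher (0.0150). Some lists that passed in neither setting turned direction too. With edgeR these were nuclear oxidative phosphorylation (0.112), mitochondrially encoded genes (0.846), mitochondrial biogenesis (0.8455) and HIF-1 targets (0.612) at 4 h, and nuclear oxidative phosphorylation (0.344), the TCA cycle (0.302) and cholesterol (0.915) at 24 h. On ranks they were HIF-1 targets (0.670) and alternative activation (0.783) at 4 h and the TCA cycle at 3 d (0.662). On log2 fold changes they were alternative activation at 4 h (0.734) and mitochondrial biogenesis at 3 d (0.996).

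Of 22 tests of marker lists 2 passed, and 14 kept direction and side of the threshold under edgeR, 17 on ranks, 22 with the larger correlation and 13 on log2 fold changes. Ranks ended the calls of the macrophage list at 24 h (cameraPR adjusted p = 0.128) and the dendritic cell list at 3 d (0.0793), and log2 fold changes ended that of macrophages at 24 h (0.9202). Log2 fold changes added mast cells and basophils, lower at 24 h (0.0202), and stromal cells, higher at 3 d (3.90e-04). The other changes were turns of lists that passed in neither setting. With edgeR these were macrophages (0.254), neutrophils (0.8455), B cells (0.642), mast cells and basophils (0.846) and stromal cells (0.312) at 4 h, and dendritic cells (0.8455), stromal cells (0.498) and osteoclasts (0.8455) at 24 h. On ranks they were neutrophils (0.593) and stromal cells (0.547) at 4 h and stromal cells at 24 h (0.929). On log2 fold changes they were neutrophils (0.892), B cells (0.808) and stromal cells (0.0810) at 4 h, and dendritic cells (0.431), stromal cells (0.333) and osteoclasts (0.981) at 24 h. For the list changes the cause was not tested.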

Other observations

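The list tests on symbol stems, the test of mitochondrial RNA capture and both tests on the scaling at 4 h were chosen after the results were seen. Genes were also grouped by the letters that begin their symbols, 165 stems of at least 10 protein-coding genes, and tested with cameraPR over 469 tests, of which 35 passed an adjusted p of 0.05. Proteasome genes outside the immunoproteasome members of the fixed list were higher too at 24 h. The Psmb group includes Psmb8, Psmb9 and Psmb10 of that list, so its adjusted p and median are not separate from it. At 24 h all 10 Psmb genes rose in the authors' deposited table (adjusted p = 4.94e-11) with a median of 1.38, and 13 of 14 Psmd genes, regulatory subunits, rose and 0 fell (adjusted p = 6.47e-08) with a median of 0.99. The medians were 0.96 and 0.58 with edgeR in the authors' deposited table. At 4 h the Psmb median was 1.07 with DESeq2 and 0.14 with edgeR in the authors' deposited table. The Psmd median was 0.68 and -0.26, so its sign turned between the tools, while the edgeR median of all tested genes was -0.97. Psmd10 (1.86), Psmb5 (1.57) and Psmd12 (1.33) are examples at 24 h in the authors' deposited table, chosen after their values were seen.

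Genes whose symbols begin with Rpl or Rps, among them the ribosomal protein genes, were mostly lower at 24 h. The Rps group also holds the kinase genes Rps6kb1 and Rps6kb2, so its values are not those of ribosomal protein genes alone. Of 54 Rpl genes 3 rose and 42 fell (adjusted p = 2.45e-07) and of 45 Rps genes 7 rose and 34 fell (adjusted p = 1.13e-05) in the authors' deposited table, with medians of -0.51 and -0.55, or -0.92 and -0.96 with edgeR. At 3 d they were lower with medians of -0.17 in both groups in the authors' deposited table, with adjusted p of 0.00822 for Rpl and 0.0261 for Rps. At 4 h neither group passed on the DESeq2 columns, with DESeq2 medians of 0.22 and 0.22 and edgeR medians of -0.72 and -0.72 in the authors' deposited table. Rpl3 (-0.91) and Rps2 (-0.70) are examples at 24 h from the authors' deposited table, chosen after their values were seen, and ribosomal protein genes have many processed copies that can share reads. The Gbp genes, interferon-induced GTPases, rose in 10 of 10 cases at 24 h in the authors' deposited table (adjusted p = 4.94e-11). Of 12 Parp genes 8 rose and 4 fell at 4 h, 8 rose and 3 fell at 24 h and 7 rose and 0 fell at 3 d in the authors' deposited tables (adjusted p = 6.95e-05, 1.38e-05 and 2.18e-07). Of 11 Ms genes, mostly of the Ms4a membrane protein family, 9 rose and 0 fell at 24 h in the authors' deposited table (adjusted p = 2.70e-04), led by Ms4a4c (8.41), with Ms4a6d at 4.01. Of 32 Kif genes, which encode kinesins, 8 rose and 21 fell at 24 h in the authors' deposited table (adjusted p = 0.00462). On the DESeq2 columns the group did not pass at 4 h (0.0548) or 3 d (0.0828).

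Mitochondrially encoded genes were lower at 24 h and 3 d, and at 3 d the nuclear oxidative phosphorylation list was lower too with edgeR (cameraPR adjusted p = 0.0201) and on ranks (0.0362) but not called with DESeq2, with no test of the difference between the lists. Reads shared with annotated nuclear copies do not account for this as a whole, because the 6 genes with under 10% shared windows had medians of -0.84 and -0.79. The higher of these, -0.79, lies below the bound of -0.3 set beforehand. Windows were compared with annotated transcripts only, so nuclear copies of these genes outside the annotation cannot be excluded. Lower capture of mitochondrial RNA, which reaches a library through its adenylated ends, may also lower these genes and cannot be told apart from a change in the cells. These 6 genes had a range of log2 changes of 1.24 at 24 h and 0.62 at 3 d, but 0 of them was called higher at either time, so neither bound was met. The range at 24 h reached down to a gene at -1.65 that was not called. The bound against lower capture asked for calls in opposite directions. It was set after 0 mitochondrially encoded genes had been seen higher at 24 h and 3 d, so it could not be met and the test cannot decide. A change in mitochondrial transcription or content with MPLA stays open as a hypothesis and was not tested, since no measure of mitochondrial DNA was used here.

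Ighm had a log2 change of -1.75 at 4 h, -8.98 at 24 h and -6.42 at 3 d in the authors' deposited tables, the largest decrease at the 2 later times by the rule for named genes. A loss of contaminating B cells could produce this, and was taken beforehand to lower light chain and J chain genes by about as much. Whether Jchain follows such a loss was not tested. Of these only Jchain was listed, at 0.24 at 4 h and -1.49 at 24 h with DESeq2 adjusted p of 0.874 and 0.269 and at -0.42 at 3 d without one in the authors' deposited tables, which is too few genes to decide. Of the B cell receptor genes, Cd79a stood at -0.20 (adjusted p = 0.9198), -0.59 and 0.28, the later 2 without an adjusted p, and Cd79b was lower at 24 h (-1.54, DESeq2 adjusted p = 4.65e-07) and higher at 3 d (0.47, adjusted p = 0.00744) in the authors' deposited tables, so Cd79b went with such a loss at 24 h and not at 3 d. The explanations cannot be told apart, because 1 of 6 listed B cell markers had an adjusted p at 3 d, and a regulated transcript of the locus in the macrophages was not tested.

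The split of higher and lower genes at 4 h differed between the tools. The difference between the DESeq2 and edgeR log2 changes in the authors' deposited table had a median of 0.94 and an interquartile range of 0.00854 across genes, so for most genes the log2 values differ by 1 constant, while the part of the calls that comes from the tools' different tests was not separated. This test was the second one tried, since the first asked whether the middle 90% of genes lay within 0.2 of the median and was not met, with a 90% span of 0.316. Which scaling is nearer to amounts per cell cannot be told, because 23.6% of tested genes had opposite signs and the table holds 0 entries for an added standard. An equal change in all RNA per cell would leave the shares of the reads as they were and so cannot give such a constant, while a few strongly induced genes taking a large share of the reads could, which was not tested.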
